A study of Mus musculus with 33 samples.

How the data were processed

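Total RNA from the livers of 33 mice, 10 on the control diet, 12 on fenofibrate and 11 on fish oil, was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array each. Per the labels' protocols, the mice were housed in pairs (2 mice per cage), each labelling used 5 µg of RNA, and the RNA integrity number was above 8. The labels do not say which mice shared a cage. The deposited table holds log2 expression values per probe set made by the authors with GCRMA 2.24.1, per the submitters' processing notes. GCRMA corrects the background with the probe sequence and normalizes between arrays by quantiles, so array medians are nearly equal by construction and small differences between dim probe sets are compressed. The values ran from 0.484 to 15.6, and the brightest probe sets lie near the top of that range, where differences can be compressed too. Array data have no sequencing depth, and the number of arrays limits the precision.

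The table has 45101 probe sets. The 64 control probe sets were left out. Of the others, 34958 carry 1 gene in the platform annotation used here, 932 carry several and 9160 are not named here. Symbols were updated through the gene identifier for 34754 probe sets with names of the mouse assembly GRCm38.p6, and the name of the annotation was kept for 204; no coordinates were used. Probe sets with a log2 value of at least 4 in at least 10 of the 33 arrays were kept, without regard to group, which left 17162. Of these 15203 carry 1 gene, and the probe set with the highest mean over all arrays stood for its gene. This gave 9005 genes, of which 3850 had more than 1 probe set past the filter. Probe sets of families with closely related members, such as Cyp4a, Cyp2c, Acot and Gst genes, can bind transcripts of relatives, so values of single members are uncertain. Genes without a probe set of their own past these steps were not analysed here.

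All comparisons were made in 1 linear model per gene over the 3 groups with limma 3.58.1 (statmod 1.5.0, R 4.3.3), using lmFit, contrasts and eBayes, two-sided, with Benjamini-Hochberg adjustment over the 9005 genes of each comparison. A gene was called changed at an adjusted p under 0.05. At an unadjusted p under 0.05 the counts were 4313 for fenofibrate against control, 2416 for fish oil against control and 4208 between the diets. The 31 gene lists were mitochondrial beta-oxidation, peroxisomal beta-oxidation, peroxisome biogenesis, microsomal omega-oxidation, acyl-CoA thioesterases, ketogenesis, fatty acid uptake, lipid droplets and lipolysis, cholesterol synthesis, fatty acid synthesis, bile acids, lipoproteins, xenobiotic metabolism, glutathione and oxidative stress defence, amino acid catabolism, glucose handling, acute phase, complement and coagulation, interferon response, cell cycle, circadian clock, respiratory chain, and markers of Kupffer cells, stellate cells, sinusoidal endothelial cells, cholangiocytes, lymphocytes, blood cells, adipocytes, pancreatic acinar cells and hepatocytes. They were tested with camera against all other genes at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, whose directional p asks for movement one way on balance and whose mixed p asks for change in either direction. P values of lists were adjusted over the 31 lists of a comparison.

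Named genes followed a rule fixed before the data were examined, as were the lists, the model and most of the alternatives; the 5 fits described last here, and the divisions and simulations by whole pairs, were added after the data were seen. The rule takes, per comparison, the 8 largest rises and the 8 largest falls among called genes, up to 4 members of each list with the smallest adjusted p, and a set of 34 genes of PPARα and lipid biology, of which 26 were measured. It gave 236 genes; exceptions are stated where they occur.

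The fit was tested on simulated data with 200 of 9005 genes changed. In the simulation of fenofibrate against control, 62% of the 50 genes changed by a log2 of 0.3 were called with the right sign, 80% at 0.5, 98% at 1 and 100% at 2. For fish oil against control the shares were 52%, 82%, 98% and 100%, and for the diets against each other 54%, 80%, 100% and 100%. Of all calls, 5.03%, 5.14% and 4.57% fell on unchanged genes. The simulated values were independent between genes and between arrays, whereas real arrays with consecutive label numbers deviate together. These shares therefore test the fit and need not hold for the real arrays. For the comparisons that share controls, 100 simulations without effect gave the correlation and covariance that shared controls produce, and the controls were split into odd and even numbers and, in all 20 ways, by whole pairs of consecutive label numbers. The alternatives chosen beforehand changed the filter, the scaling, the probe set of a gene, the variance model, the arrays in the fit, array weights, the replicate number as a block, consecutive array label numbers as a random block, the arrays whose label number carries the letter A, the threshold and the size of change, and left out each array in turn. Added ones took the label number as a covariate, fitted arrays numbered 1 to 16 and 17 to 34 alone, and left out control replicate 9 or control replicates 1, 2 and 9. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.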

Results

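Liver RNA from 33 male C57BL/6J mice was measured, with 1 Affymetrix Mouse Genome 430 2.0 array per mouse. The mice were 17 weeks old and had received their diet for 2 weeks. The control diet of 10 mice held sunflower oil rich in oleic acid at 7% of energy. The 12 mice of the fenofibrate group received that diet with 0.03% (w/w) fenofibrate, a lipid-lowering drug that activates the nuclear receptor PPARα. The 11 mice of the fish oil group received fish oil in place of the sunflower oil, also at 7% of energy; EPA made up 23.1% of it and DHA 21.1%. The series compares the liver transcriptome after the drug with that after the oil. Arrays hold no read depth, and the number of arrays limits the precision. The median over all probe sets lay between 2.9 and 2.97 (log2) on every array, and between 16401 and 16781 probe sets reached a log2 value of 4. Arrays of one diet correlated with each other across genes at 0.968 to 0.995, and no 2 arrays held identical values. Changes below are log2 differences between group means ± SE from the model of all 33 arrays. That model takes the arrays as independent. Arrays with consecutive label numbers deviated together, so these SE and the adjusted p values can be too small. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05 in limma.

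In the comparison of fenofibrate (n = 12) with control (n = 10), genes of fatty acid oxidation rose together. Of 19 measured genes of mitochondrial beta-oxidation, 17 rose, 0 fell and 2 did not pass the test, with a median difference of 0.63. Among them were Eci1 (1.31 ± 0.07, 2.48-fold), Decr1 (1.04 ± 0.05), which handles unsaturated fatty acids, Hadha (0.82 ± 0.06) and Acadvl (0.59 ± 0.04). Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, was among the genes that did not pass (-0.07 ± 0.07). Of 16 peroxisomal beta-oxidation genes, 11 rose and 1 fell, Pecr, which was named after its values were seen. Ehhadh rose from 11.85 ± 0.67 (SD) to 14.24 ± 0.06, a difference of 2.39 ± 0.18, and Ech1 rose by 1.13 ± 0.06. The camera test passed for both lists, with adjusted p = 1.76e-16 and 5.90e-06; with an estimated correlation these were adjusted p = 0.0274 and adjusted p = 0.0840.

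The largest rises were in Cyp2b9 (7.33 ± 0.81), a cytochrome P450 of steroid and drug metabolism, and Mogat1 (6.56 ± 0.17), a monoacylglycerol acyltransferase. Cox6b2 (5.82 ± 0.18), Rad51b (5.63 ± 0.55), Krt23 (5.63 ± 0.29), Vldlr (5.62 ± 0.44), Ly6d (4.70 ± 0.37) and Cyp4a31 (4.36 ± 0.29) followed. The probe set of Mogat1 is 1419504_at, and its mean rose from 2.49 ± 0.33 (SD) to 9.05 ± 0.59. The control means of Mogat1, Cox6b2, Krt23, Ly6d and Cyp2b9 lay below 4, so their fold depends on how the authors' background model treats dim probe sets. The largest falls were in Hsd3b5 (fell by 7.19 ± 0.68), a hydroxysteroid dehydrogenase, and Slc22a7 (fell by 4.50 ± 0.25), an organic anion transporter. Falls followed in Serpina12 (-4.49 ± 0.45), Serpina4-ps1 (-3.97 ± 0.50), Tff3 (-3.94 ± 0.64), Sdr9c7 (-3.39 ± 0.21), Enho (-3.19 ± 0.21) and Scara5 (-2.9 ± 0.59). For Cyp2b9 and Hsd3b5 the array of control replicate 9 stood apart, at 9.69 and 5.34, against means of 2.95 and 11.57 over all 10 controls.

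**Figure D1:**
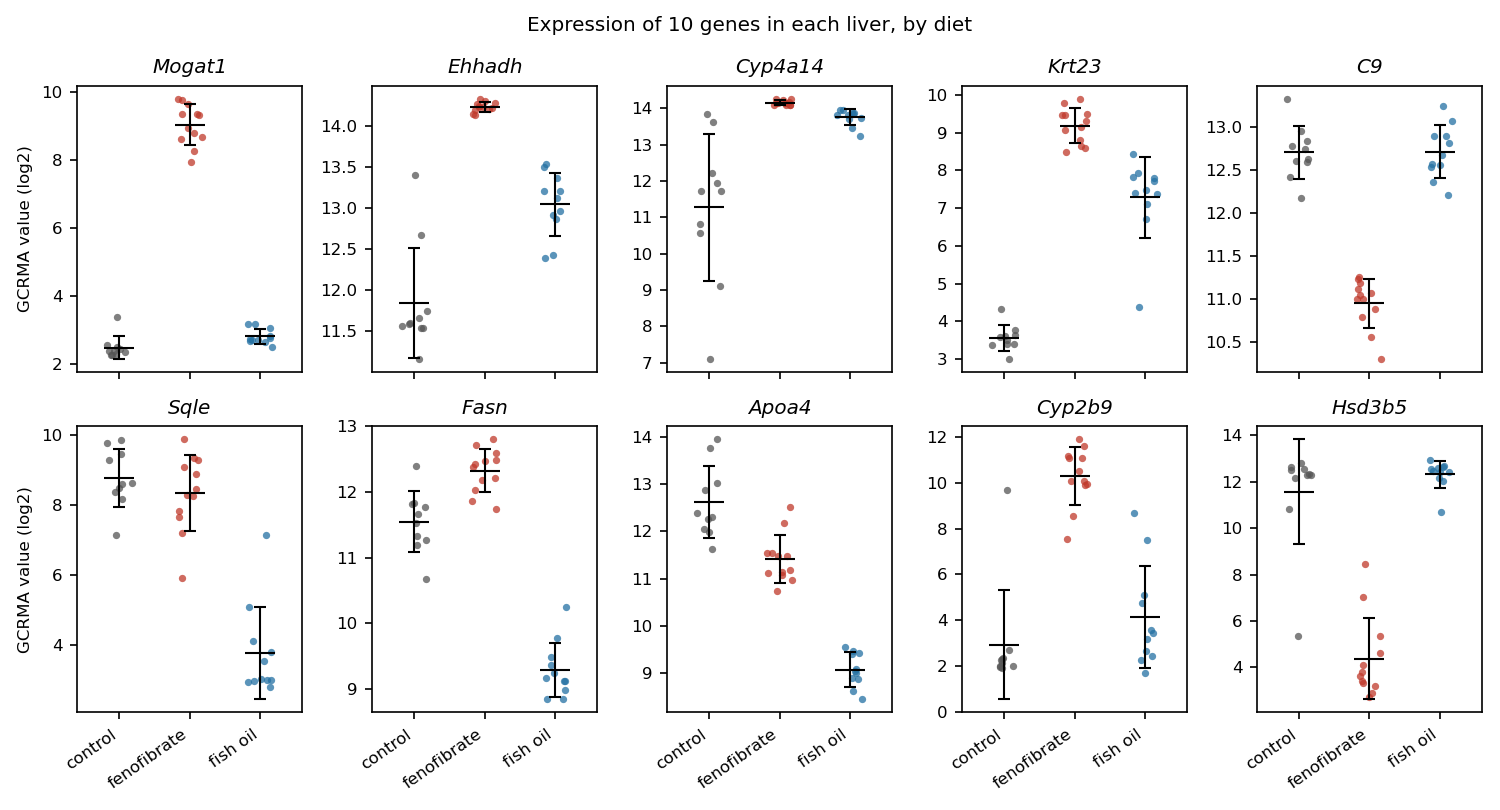
Log2 GCRMA value (vertical axis) of 10 genes in each liver, with 1 point per mouse for control (n = 10), fenofibrate (n = 12) and fish oil (n = 11); black lines are group means and SD, and each panel has its own scale. Mogat1 lay at 9.05 on fenofibrate against 2.49 in controls, Sqle at 3.77 on fish oil against 8.78, and 1 control mouse lay with the fenofibrate mice in Cyp2b9 and Hsd3b5.

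Genes of fatty acid uptake and storage also moved on fenofibrate. In the list of fatty acid uptake, binding and activation, 14 of 20 genes rose and 3 fell. Slc27a1 rose by 4.20 ± 0.15, the fatty acid translocase Cd36 by 3.32 ± 0.17 and lipoprotein lipase Lpl by 3.29 ± 0.21. Slc27a1 reached at most 3.78 in controls, so its fold also depends on how the background model treats dim probe sets. Of 11 acyl-CoA thioesterases, 9 rose and 1 fell, led by Acot1 (3.41 ± 0.29), Acot2 (3.37 ± 0.32) and Acot8 (1.37 ± 0.10). Of 20 genes of lipid droplets and lipolysis, 13 rose and 2 fell. Besides Mogat1, the monoacylglycerol lipase Mgll rose by 0.88 ± 0.08, the droplet protein Cidec by 3.90 ± 0.53 and Plin2 by 0.34 ± 0.12 (0.54 without control replicates 1, 2 and 9). These 3 lists passed camera with adjusted p = 1.08e-05, 6.24e-06 and 1.42e-05, and also with an estimated correlation (adjusted p = 0.00668, 0.0471 and 0.0386). Pdk4, which inhibits the pyruvate dehydrogenase complex, rose by 2.96 ± 0.42, and the pantetheinase Vnn1 rose by 2.18 ± 0.17. The receptor gene Ppara itself did not pass the test (0.01 ± 0.08), while Pparg rose by 0.87 ± 0.15 from a dim mean of 5.02 and Rxra fell by 0.36 ± 0.07. Angptl4 (-0.20 ± 0.10), Ppargc1a (-0.31 ± 0.23) and Mlxipl (-0.08 ± 0.07) did not pass.

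Of 13 peroxisome biogenesis genes, 7 rose and 1 fell on fenofibrate, led by Pex11a (1.34 ± 0.15), which acts in peroxisome division. Of 30 respiratory chain genes, 24 rose and 0 fell, by small amounts, with Uqcrc2 at 0.40 ± 0.04. Both lists passed camera (adjusted p = 0.0177 and 5.24e-08), and lost the call at adjusted p = 0.183 and adjusted p = 0.104 with an estimated correlation. Of 9 genes of microsomal omega-oxidation, 4 rose and 4 fell: Cyp4a31, Cyp4a14 (2.89 ± 0.46), Cyp4a12a (1.96 ± 0.21) and Aldh3a2 (1.97 ± 0.16) rose, while Cyp4f14 fell by 2.16 ± 0.10. In the ketogenesis list, 3 of 5 genes rose, Acat1 (0.60 ± 0.05) among them, and 1 fell, Bdh2 (fell by 0.94 ± 0.22); Fgf21 did not pass (-0.10 ± 0.40). Neither of these lists passed camera (adjusted p = 0.539 and 0.163).

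Of 21 genes of fatty acid synthesis and desaturation, 13 rose and 0 fell on fenofibrate. Malic enzyme Me1 rose by 1.23 ± 0.10, Pgd by 0.80 ± 0.08, Fasn by 0.78 ± 0.17 and Fads2 by 0.52 ± 0.09, whereas Scd1 did not pass on its brightest probe set, at 14.33 in controls (0.10 ± 0.04), and rose by 0.39 on another (adjusted p = 0.00700 over all probe sets). The list passed camera (adjusted p = 6.50e-04), but not with an estimated correlation (adjusted p = 0.161). Of 20 genes of cholesterol synthesis and uptake, 2 rose, Hmgcs1 (0.65 ± 0.18) and Fdft1 (0.40 ± 0.14), and 18 did not pass (camera adjusted p = 0.417). The lipogenic transcription factor gene Srebf1 rose by 0.44 ± 0.17 (adjusted p = 0.0364), and lost the call without control replicate 1, 2 or 9 or fenofibrate replicate 3, 7, 11 or 12 (adjusted p up to 0.0917); without control replicates 1, 2 and 9 its adjusted p was 0.475. The call of Fdft1 was lost without control replicate 9 (adjusted p = 0.0539) and without control replicate 2 (adjusted p = 0.0609). Over the alternatives its adjusted p ran up to 0.166, without control replicates 1, 2 and 9.

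Complement and coagulation genes, which encode plasma proteins of the liver, formed the list with the smallest camera p at the preset correlation for fenofibrate against control. Of 31 measured members, 30 fell and 0 rose, with a median difference of -0.48. The terminal complement genes C8a (fell by 1.21 ± 0.11) and C9 (fell by 1.76 ± 0.12, 3.38-fold) fell with C4bp (fell by 1.01 ± 0.06) and C1ra (fell by 0.76 ± 0.05). Camera gave adjusted p = 2.91e-24, and adjusted p = 0.0144 with an estimated correlation. Of 14 hepatocyte markers, 9 fell and 0 rose, with a median of -0.16; 7 of the 14 also stand in another list. Ahsg fell by 0.49 and Hnf4a fell by 0.42. The hepatocyte list passed camera (adjusted p = 9.87e-05), also with an estimated correlation (adjusted p = 0.0471, but adjusted p = 0.0578 without control replicates 1, 2 and 9). Medians for markers of other liver cell types were -0.24 for 14 Kupffer cell genes (3 fell, Clec4f by 0.43 ± 0.10), -0.24 for 11 stellate cell genes (6 fell, Rgs5 by 0.57 ± 0.06, and 1 rose) and -0.12 for 14 sinusoidal endothelial genes (5 fell and 1 rose). Camera gave adjusted p = 0.0381, 0.0240 and 0.125 for these lists; with an estimated correlation the Kupffer cell list had adjusted p = 0.533 and the stellate cell list adjusted p = 0.130. Without control replicates 1, 2 and 9 both calls were lost, at adjusted p = 0.130 and 0.0617. The Kupffer cell call was also lost with a stricter filter, with centred arrays and without control replicate 9 (adjusted p = 0.0511, 0.0578 and 0.0555), and the stellate cell call without a filter (adjusted p = 0.0828).

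Of 32 genes of amino acid catabolism and the urea cycle, 19 fell and 2 rose on fenofibrate. Carbamoyl phosphate synthetase Cps1 fell by 0.45 ± 0.04, Gnmt by 0.50 ± 0.05 and Cbs by 0.66 ± 0.08. Of 19 genes of bile acid synthesis and transport, 12 fell and 5 rose: the uptake carrier Slco1a1 fell by 2.50 ± 0.21, while the export pump Abcc3 rose by 1.46 ± 0.16. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.16 ± 0.43, and lost the call without control replicate 9 (adjusted p = 0.0569) and without control replicate 1, fenofibrate replicate 5 or fenofibrate replicate 6 (adjusted p up to 0.0584), and over the alternatives its adjusted p ran up to 0.0931. Of 22 lipoprotein genes, 11 fell and 3 rose, with Pltp at 1.80 ± 0.12, Apom (fell by 0.65 ± 0.04) and Scarb1 (fell by 0.58 ± 0.06) among them. These lists passed camera in the downward direction (adjusted p = 1.06e-05, 0.0278 and 0.0139), and had adjusted p = 0.108, 0.161 and 0.161 with an estimated correlation. Of 27 genes of glutathione and oxidative stress defence, 14 rose and 3 fell (camera adjusted p = 0.00326, and adjusted p = 0.166 with an estimated correlation); Gstm4 rose by 1.22 ± 0.11 and Ephx1 by 1.21 ± 0.12.

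Immune lists were lower on fenofibrate. Of 23 acute phase genes, 13 fell, such as Itih4 (fell by 0.72 ± 0.09) and Crp (fell by 0.50 ± 0.07), and 1, Il1rn, rose. Control replicates 1 and 2 stood apart in this list, with median deviations of 1.02 and 1.29 from the 7 controls other than replicates 1, 2 and 9, each of which deviated by -0.07 to 0.19. Without those 3 controls, 11 acute phase genes fell and 2 rose, and the median moved from -0.48 to -0.23. Of 22 genes of the interferon response and antigen presentation, 12 fell and 0 rose, with Irf7 (fell by 1.05 ± 0.11) and Oas1a (fell by 0.87 ± 0.12). Both lists passed camera (adjusted p = 3.80e-04 and 2.16e-04), and had adjusted p = 0.363 and adjusted p = 0.298 with an estimated correlation.

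The other lists did not pass camera on fenofibrate. Of 15 xenobiotic metabolism genes, 7 rose and 3 fell, with Cyp2b9 higher and Cyp2c54 (fell by 2.65 ± 0.27) and Cyp2c50 (fell by 1.44 ± 0.13) lower (adjusted p = 0.974). Of 20 genes of glucose handling, 4 rose and 7 fell, among them the liver pyruvate kinase Pklr (fell by 1.37 ± 0.18; list adjusted p = 0.20). Of 12 cell cycle genes, 5 rose and 2 fell, with Mcm4 at 1.04 ± 0.16 from a dim mean of 3.98 (list adjusted p = 0.174, and adjusted p = 0.00248 with no filter on dim probe sets). Of 14 circadian clock genes 1 fell (list adjusted p = 0.214). Control replicates 1, 2 and 9 had clock medians of -1.03, -0.54 and -0.49 relative to the other controls, and without them 9 clock genes fell, 1 rose and the list passed camera (adjusted p = 0.00967; adjusted p = 0.20 with an estimated correlation). Few members of the remaining marker lists were measured. Of 2 cholangiocyte genes Krt23 rose (the list passed camera with the stricter filter, adjusted p = 0.00835), of 3 adipocyte genes Cidec and Fabp4 rose and Car3 fell, and of 4 blood cell genes Bpgm rose and Alas2 fell. Control replicates 1 and 2 stood apart in the adipocyte list, with medians of 1.02 and 1.30 (-0.22 to 0.15 in the controls other than replicates 1, 2 and 9). Without control replicates 1, 2 and 9, 2 adipocyte genes still rose and 1 fell. The single pancreatic acinar gene, Cela1, fell by 1.13 ± 0.18. The single lymphocyte gene, Ighm, rose (0.67 ± 0.25), a call that was lost without control replicate 1, 3, 4, 8 or 9 or without fenofibrate replicate 1 or 3 (highest adjusted p = 0.0677).

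In all, 3676 of 9005 genes changed on fenofibrate (limma), 1978 higher and 1698 lower, and 262 of them changed at least 2-fold. The median size of these changes was 0.34. Adjusted over the list alone, the counts of higher and lower members stayed as given for mitochondrial and peroxisomal beta-oxidation and for complement, and were 16 lower in the acute phase list and 15 higher in fatty acid synthesis. Without control replicates 1, 2 and 9, a choice made after the data were seen, 3776 genes changed, 3173 of them also called with all arrays.

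In the comparison of fish oil (n = 11) with control (n = 10), genes of lipid synthesis fell. All 20 measured genes of cholesterol synthesis and uptake were called lower, with a median difference of -1.40. Squalene epoxidase Sqle fell by 5.01 ± 0.46, from 8.78 ± 0.83 (SD) to 3.77 ± 1.31, Fdps by 2.71 ± 0.26 and Idi1 by 2.58 ± 0.28. The fish oil mean of Sqle lay below 4, so the size of its fall depends on how the background model treats dim probe sets. The transcription factor gene Srebf2, which drives cholesterol synthesis, fell by 0.69 ± 0.15, and Srebf1 fell by 0.58 ± 0.17 (adjusted p = 0.0197, and up to 0.0580 over the alternatives). Mlxipl rose by 0.23 ± 0.08 (adjusted p = 0.0348), and lost the call without control replicate 3, 5, 7 or 9 or fish oil replicate 1, 2, 3, 5 or 11 (adjusted p up to 0.0754) and without control replicates 1, 2 and 9 (adjusted p = 0.120). Of 21 genes of fatty acid synthesis and desaturation, 18 fell and 1 rose, with a median of -0.98. Fatty acid synthase Fasn fell by 2.26 ± 0.17 (4.79-fold), Acacb by 2.17 ± 0.14, and the desaturases Fads2 and Fads1 by 1.61 ± 0.09 and 1.55 ± 0.09. Camera gave adjusted p = 1.05e-32 for the cholesterol list and 1.42e-31 for the fatty acid list; with an estimated correlation these were adjusted p = 0.00901 and adjusted p = 3.33e-05.

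The largest fall on fish oil was in Cyp17a1 (probe set 1417017_at), a steroid hydroxylase, which fell by 5.59 ± 0.29 from 9.69 ± 0.99 (SD) to 4.10 ± 0.55. That fish oil mean lay near the filter level of 4, so the size of this fall also depends on the background model. Tff3 fell by 3.67 ± 0.65, the apolipoprotein gene Apoa4 by 3.56 ± 0.23, the lysolipid transporter gene Mfsd2a by 3.11 ± 0.49 and Fabp5 by 2.60 ± 0.27. Fgf21, a hormone of the liver, fell by 2.22 ± 0.41 to a mean of 2.96, within the range of the array medians, and Ccnd1, a cyclin of the cell cycle list, fell by 1.87 ± 0.19. RIKEN clones aside, the largest rises were in Krt23 (3.73 ± 0.29) and Rad51b (2.57 ± 0.56). Cyp4a14 (2.48 ± 0.47), Clec2h (1.82 ± 0.44), Acot1 (1.73 ± 0.29), the metallothionein gene Mt2 (1.67 ± 0.53), Gpat3 (1.63 ± 0.38) and Gsta2 (1.61 ± 0.22) followed. Without control replicates 1, 2 and 9 the rise of Clec2h was 0.81 and that of Gpat3 2.47, and with array weights the rise of Clec2h was 1.19. The call of Mt2 (adjusted p = 0.0311) was lost without control replicate 3, 4, 6, 7, 8 or 10 or fish oil replicate 4, 9 or 10 (adjusted p up to 0.0623).

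Fatty acid oxidation genes also rose on fish oil. Of 19 mitochondrial beta-oxidation genes, 16 rose and 1 fell, with a median of 0.31: Eci1 rose by 0.55 ± 0.07, Decr1 by 0.48 ± 0.05 and Acadvl by 0.31 ± 0.04, and the gene that fell was Cpt1a (fell by 0.34 ± 0.07). Of 16 peroxisomal genes, 10 rose and 0 fell, led by Ehhadh (1.20 ± 0.18), Crot (0.66 ± 0.08) and Ech1 (0.56 ± 0.06). Of 9 omega-oxidation genes, 6 rose and 0 fell, with Cyp4a31 at 1.59 ± 0.30, Cyp4a12a at 1.36 ± 0.22 and Aldh3a2 at 0.80 ± 0.16. Camera passed for these lists (adjusted p = 8.83e-14, 1.39e-07 and 2.57e-05), also with an estimated correlation (adjusted p = 0.0360, 0.0430 and 0.00901). Vnn1 rose by 1.25 ± 0.17. Other oxidation lists held few calls: 4 of 11 thioesterases rose and 1 fell, 4 of 13 peroxisome biogenesis genes rose, Pex11a (0.55 ± 0.15) among them, and 2 of 5 ketogenesis genes rose and 1, Fgf21, fell (camera adjusted p = 0.206, 0.0704 and 0.342).

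Several further lists shifted on fish oil. Of 14 sinusoidal endothelial markers, 5 fell and 0 rose (8 fell when adjusted over the list alone), with Flt4 (fell by 0.42 ± 0.07) and Clec4g (fell by 0.24 ± 0.06) among them; camera gave adjusted p = 6.10e-05, and adjusted p = 0.0204 with an estimated correlation. Kupffer cell markers (0 of 14 called), stellate cell markers (1 of 11 fell) and hepatocyte markers (4 of 14 fell) did not pass camera (adjusted p = 0.597, 0.206 and 0.206). Of 27 genes of glutathione and oxidative stress defence, 9 rose and 3 fell, with Gsta2 and Ephx1 (1.18 ± 0.13) higher and Gstm2 lower (fell by 1.21 ± 0.15). Of 15 xenobiotic metabolism genes, 6 rose and 1 fell. Of 22 lipoprotein genes, 8 fell and 2 rose; Pltp fell by 1.06 ± 0.12 and Apoc2 by 0.60 ± 0.06. Of 22 interferon and antigen presentation genes, 7 fell and 0 rose, such as Oas1a (fell by 0.63 ± 0.13) and Irf7 (fell by 0.48 ± 0.11), and of 31 complement and coagulation genes, 6 fell and 1 rose. These 5 lists passed camera (adjusted p = 0.0233, 0.0164, 0.00167, 1.38e-04 and 0.0375) and lost the call with an estimated correlation, at adjusted p = 0.378, 0.378, 0.0811, 0.378 and 0.621. So did the cholangiocyte list of Krt23 and Sox9 (adjusted p = 0.0263, and adjusted p = 0.0615 with an estimated correlation), which also lost the call with no filter on dim probe sets (adjusted p = 0.183) and without control replicates 1, 2 and 9 (adjusted p = 0.0506).

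The list of fatty acid uptake, binding and activation was split on fish oil. Of 20 genes, 6 rose, such as Lpl (0.77 ± 0.21), and 8 fell, such as Acsl3 (fell by 1.64 ± 0.16) and Fabp5 (camera adjusted p = 0.117). Of 19 bile acid genes, 3 rose and 4 fell, with Abcc3 at 1.53 ± 0.16 (adjusted p = 0.939). In lipid droplets and lipolysis, amino acid catabolism and glucose handling, 2, 4 and 1 genes rose and 2, 7 and 1 fell; the last was Pklr (fell by 1.22 ± 0.18). The acute phase list had 1 rise and 2 falls, the cell cycle list 1 fall, the respiratory chain 2 rises and 1 fall, and the circadian clock list 0 of either. Of these lists none passed camera (lowest adjusted p = 0.0974, for the cell cycle). Without control replicates 1, 2 and 9, the clock list had 2 rises and 5 falls and passed camera (adjusted p = 0.0285). Glucose handling, with 1 rise and 6 falls, also passed without these 3 arrays (adjusted p = 0.0360), as did the thioesterases (adjusted p = 0.0345) and peroxisome biogenesis (adjusted p = 0.0360, and adjusted p = 0.0190 without control replicate 9 alone and 0.00888 with no filter). With an estimated correlation each of these 4 lists had adjusted p = 0.361 without the 3 arrays. The acute phase list passed downward without the arrays of the letter A (adjusted p = 0.0113), and ketogenesis with the stricter filter (adjusted p = 0.0454). Without control replicates 1, 2 and 9, however, the acute phase list had 5 rises, 2 falls and a median of 0.07, and did not pass camera (adjusted p = 0.410). In the lymphocyte, adipocyte and pancreatic acinar lists 0 genes were called, and in the blood cell list 1.

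In all, 1308 genes changed on fish oil (limma), 678 higher and 630 lower, and 98 of them changed at least 2-fold, 27 higher and 71 lower. When arrays of consecutive label numbers were treated as a random block, the count was 845. Without control replicates 1, 2 and 9, 1435 genes changed, 1001 of them also called with all arrays.

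**Figure D2:**
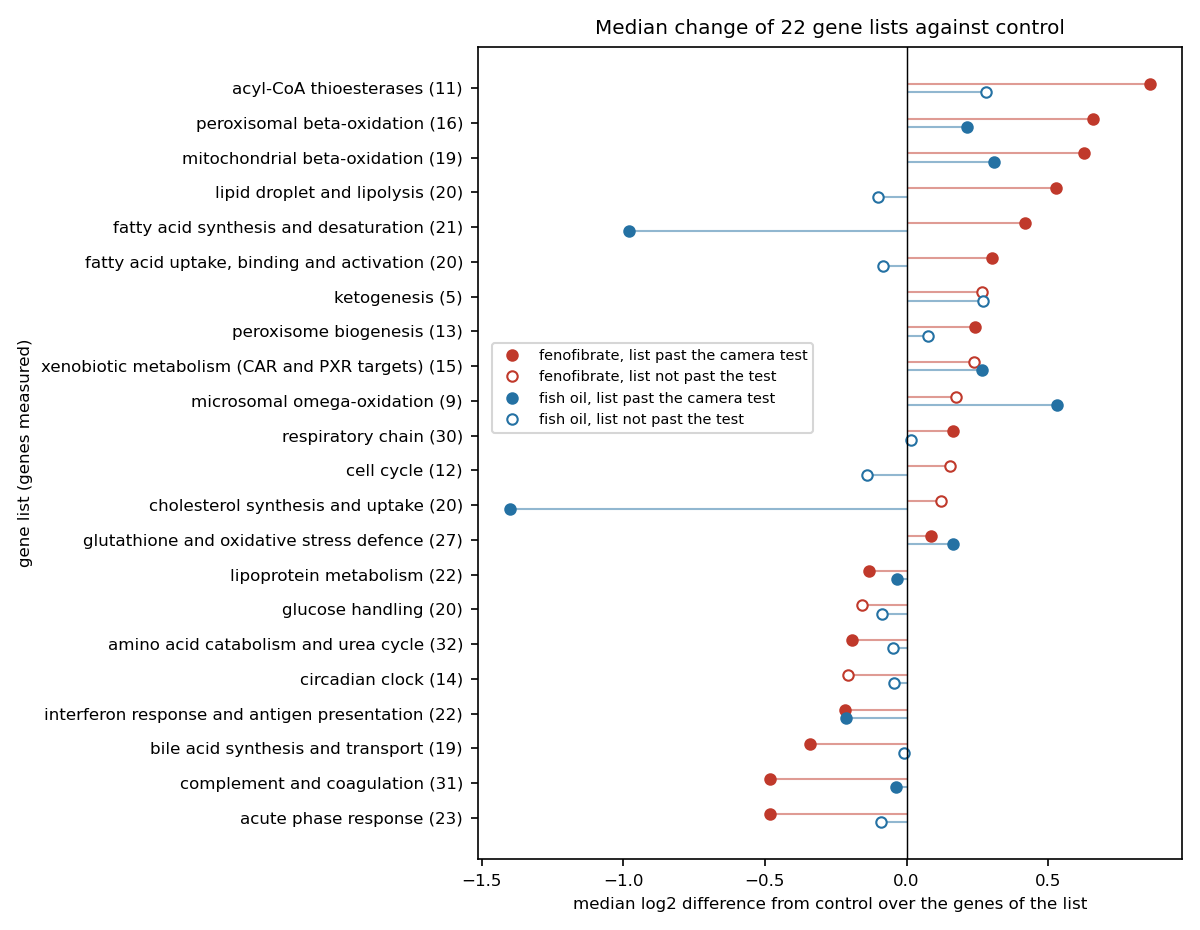
Median log2 difference from control (horizontal axis) over the measured genes of 22 lists (vertical axis, number of genes in brackets) for fenofibrate and fish oil; filled points are lists past the camera test with its preset correlation. Cholesterol synthesis lay at -1.40 on fish oil and 0.12 on fenofibrate, and complement and coagulation at -0.48 on fenofibrate and -0.04 on fish oil.

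The contrast of fenofibrate (n = 12) with fish oil (n = 11) tested for each gene whether the changes against control differed, since the controls cancel in it. All 20 cholesterol genes were called higher on fenofibrate than on fish oil (median 1.68), with Sqle at 4.57 ± 0.44, Fdps at 2.95 ± 0.25 and Pmvk at 2.21 ± 0.17. Of 21 fatty acid synthesis genes, 19 were higher and 1 lower (median 1.40); Fasn differed by 3.04 ± 0.16 (8.22-fold), Acacb by 2.89 ± 0.14 and Fads2 by 2.13 ± 0.09. Camera gave adjusted p = 1.31e-17 and 5.32e-21, and with an estimated correlation adjusted p = 0.0633 and adjusted p = 4.22e-04. The largest positive differences were Mogat1 (6.23 ± 0.17), Cyp2b9 (6.15 ± 0.79), Cyp17a1 (6.00 ± 0.27), Ly6d (5.51 ± 0.36), Cox6b2 (5.48 ± 0.17), Cidec (4.86 ± 0.52), Sqle and Vldlr (4.49 ± 0.42). The largest negative ones were Hsd3b5 (-7.94 ± 0.66), Slc22a7 (-4.25 ± 0.25), Clec2h (-4.22 ± 0.42), Serpina4-ps1 (-3.72 ± 0.48), Serpina12 (-3.56 ± 0.44), Enho (-3.52 ± 0.21), Sdr9c7 (-3.51 ± 0.20) and Cyp2c54 (-3.37 ± 0.27). Since the fish oil means of Sqle and Cyp17a1 were dim, the sizes of their differences depend on the background model.

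Fatty acid uptake and lipid droplet genes were also higher on fenofibrate, with 13 of 20 and 14 of 20 members called higher and 2 and 1 lower. Cd36 differed by 2.96 ± 0.17, Slc27a1 by 3.60 ± 0.15 and Mgll by 0.99 ± 0.08 (camera adjusted p = 2.24e-08 and 3.45e-07; adjusted p = 3.37e-04 and 0.0144 with an estimated correlation). Of 31 complement and coagulation genes, 28 were lower on fenofibrate and 0 higher, with C9 at -1.76 ± 0.12 (adjusted p = 5.32e-21, and adjusted p = 0.0144 with an estimated correlation). Mitochondrial beta-oxidation genes were higher in 17 of 19 cases and lower in 0, with Eci1 at 0.76 ± 0.07, and 9 of 11 thioesterases were higher, with Acot1 at 1.68 ± 0.28. In the respiratory chain list 22 of 30 genes were higher and 1 lower, and in the cell cycle list 6 of 12 were higher, Ccnd1 (2.01 ± 0.18) among them. Peroxisomal beta-oxidation was mixed, with 10 higher, such as Ehhadh (1.19 ± 0.17) and Crat (1.32 ± 0.17), and 5 lower. These 5 lists passed camera (adjusted p = 8.04e-09, 1.08e-05, 9.45e-08, 0.0117 and 0.0298) but not with an estimated correlation (adjusted p = 0.101, 0.0633, 0.101, 0.101 and 0.384). Amino acid catabolism (16 of 32 lower, 1 higher), hepatocyte markers (7 of 14 lower, 1 higher), the acute phase list (9 of 23 lower, 1 higher) and bile acid genes (8 of 19 lower, 2 higher) passed camera downward, at adjusted p = 5.28e-05, 0.00170, 0.0156 and 0.0298. With an estimated correlation they had adjusted p = 0.137, 0.101, 0.551 and 0.169. The acute phase call was also lost without the 5 arrays whose label number carries the letter A (adjusted p = 0.124), and the cell cycle call with a stricter filter on dim probe sets (adjusted p = 0.248). Over the 31 lists and 3 comparisons, camera passed for 18 lists on fenofibrate, 12 on fish oil and 14 between the diets, and with an estimated correlation for 6, 6 and 4. The fry test, which asks whether the members of a list move on balance one way, passed for 25, 15 and 26. In 7 of the 93 list comparisons the median, the mean and the test differed in sign, and 0 of these passed the test. In all, 3507 genes differed between the 2 diets (limma), 1786 higher and 1721 lower on fenofibrate, 277 of them at least 2-fold.

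A total of 831 genes changed on both diets against control. Of these 423 rose on both, 259 fell on both, 102 rose on fenofibrate and fell on fish oil, and 47 did the reverse. Among the genes that rose on both were 16 of mitochondrial beta-oxidation, 7 of peroxisomal beta-oxidation, 4 of omega-oxidation and 4 thioesterases, with Krt23 (5.63 and 3.73), Acot1 (3.41 and 1.73), Vnn1 (2.18 and 1.25) and Abcc3 (1.46 and 1.53) as examples. Among those that rose on fenofibrate and fell on fish oil were 12 genes of fatty acid synthesis, such as Fasn (0.78 and -2.26) and Me1 (1.23 and -0.56), 2 of cholesterol synthesis, and Pltp (1.80 and -1.06). Clec2h (-2.40 and 1.82) and Cyp4v3 (-0.62 and 0.53) went the other way. Of the 423 genes that rose on both diets, 184 differed between the diets, 172 with the larger rise on fenofibrate and 12 with the larger rise on fish oil.

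Both comparisons used the same 10 control arrays, which by itself makes their differences alike. Independent lists of these sizes would share 149 genes higher on both and 119 lower on both, and 138 and 128 in the opposite directions. The Pearson correlation of the differences across the 9005 genes, which are not independent replicates, was 0.32, against a mean of 0.53 in 100 simulations without any diet effect (0.12 to 0.82). Their covariance was 0.0410, against 0.00787 in the simulations, a difference of 0.0331. Simulations that kept pairs of consecutive label numbers whole gave a mean of 0.00916 and at most 0.0207. Both kinds shuffled deviations over all diets, which spreads those of control replicates 1, 2 and 9. They can therefore understate what the shared controls add, and the difference does not measure a shared effect of the diets. With the controls split between the comparisons, 5 arrays each, 238 and 167 genes rose on both diets in the 2 arrangements (58.5 and 57.1 for independent lists), 121 and 80 fell on both (44.7 and 46.0), and 58 and 81 went in opposite directions (103 and 103). That division by odd and even numbers put 1 array of each pair of consecutive label numbers in each comparison, so deviations shared by a pair stayed in both. In the 20 divisions by whole pairs, chosen after the data were seen, 126 to 283 genes rose on both diets and 66 to 144 fell on both, more than for independent lists in 20 of 20 divisions. Genes in opposite directions numbered 54 to 275, fewer than for independent lists in 18 of 20. In these divisions, where no control array entered both comparisons, the covariance ran from 0.00206 to 0.0443, with a median of 0.0285. With consecutive label numbers as a random block, 445 genes changed in the same direction on both diets, against 682 in the fit without it. Without control replicates 1, 2 and 9 there were 857, 513 higher and 344 lower, with 121 in opposite directions.

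**Figure D3:**
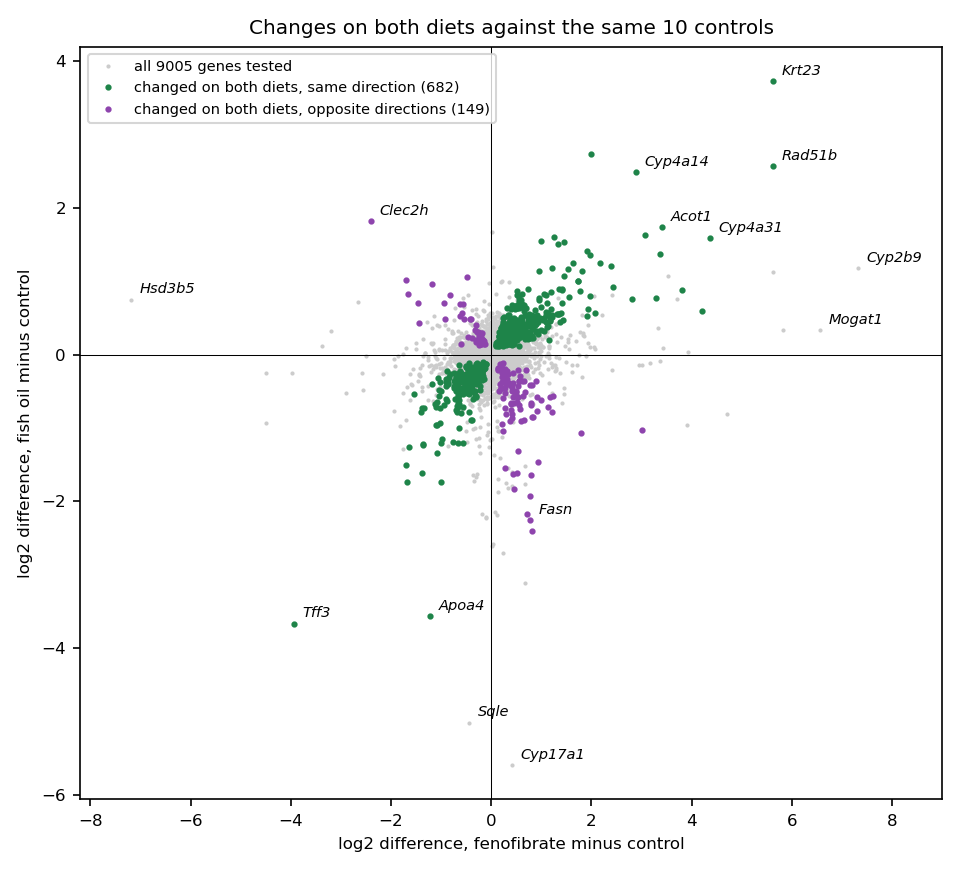
Log2 difference from control on fenofibrate (horizontal axis) against that on fish oil (vertical axis), with 1 point per gene for the 9005 genes tested; green genes changed in the same direction on both diets and purple genes in opposite directions. Of the coloured genes 682 are green, with Krt23 at 5.63 and 3.73, and 149 are purple, with Fasn at 0.78 and -2.26; the same controls enter both axes.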

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

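The tests on control replicate 9, those that leave out control replicate 9 or control replicates 1, 2 and 9, and the splits that keep pairs of arrays whole were chosen after the result was seen. Chance splits of the arrays were tested for the 3 counts of changed genes. Of 100 splits, the real one included, 1 gave as many genes as the real count for fenofibrate against control (3676, highest other 1632), 1 for fish oil against control (1308, highest other 606) and 1 for the diets against each other (3507, highest other 1105). Splits of single arrays break up arrays with consecutive label numbers, which share a diet and deviate together. Of 100 splits that kept these pairs whole, 1 gave as many genes as the real one in each comparison, with 2974, 828 and 2149 genes as the highest other counts. Chance division of single arrays or of pairs is argued against for the 3 counts, though 1 in 100 is the smallest share that 100 splits can give. Splits by pairs reached higher counts than those of single arrays. With 11, 10 and 11 pairs, some of these splits lie close to the real one and can keep part of the diet difference.

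Among the genes named in the text, 18 had a control array far from the other 9 controls; chance gives such a gap in about 1 in 20 groups, or 6.55 here. Control replicate 9 was that array for 12 genes. It was highest for Cd36 (10.5), Cyp2b9 (9.69), Ech1 (12.7), Eci1 (11.4), Mogat1 (3.39) and Vldlr (7.47). It was lowest for Cela1 (8.20), Fabp5 (11.6), Hsd3b5 (5.34), Mlxipl (10.1), Serpina12 (10.2) and Slco1a1 (10.3). Control replicate 1 was highest for Cbs (11.6), Pdk4 (9.27) and Srebf2 (7.07) and lowest for Cyp2c50 (12.0) and Pecr (11.0). Control replicate 2 was lowest for Acat1 (12.1). Fenofibrate and fish oil arrays were not searched in this way.

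Control replicate 9 deviated from the other controls in genes that fenofibrate changes. Across 3754 genes called without it, the slope of its deviations on the fenofibrate difference was 0.434 (SE over genes 0.00901), against -0.139 to 0.251 for the other controls. Genes are not independent replicates, so that SE does not measure the spread between mice. A fenofibrate liver under a control label would give a slope near 1, so the slope argues against that explanation as a whole. RNA of a fenofibrate liver mixed in may still account for part of it: over the 43 genes raised at least 4 times, the implied share had quartiles of 6.33% and 46.9%, too uneven to be one share within a factor of 3 and too close to be ruled out by the factor of 10 set for it, so this explanation cannot be told apart from a different state of that liver. Over these 43 genes the implied shares ran from -7.66% to 119%. The test was first made on the 8 largest rises alone, whose shares ran from 0.249% (Cox6b2) to 50.5% (Cyp2b9), and was then widened to the 43 genes. Krt23 (0.298%) and Mogat1 (0.936%) also implied small shares. These genes and Cox6b2 have control means below 4, and the 8 were picked for size, so they do not decide the question. Genes that fall were not weighed: Hsd3b5 lay at 5.34 on this array, against 10.8 in the next lowest control. No biological explanation was tested, since the design names none for a single control.

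In lists of genes known to differ between male and female mouse liver, written after some members had been seen, 10 of 14 male-biased genes fell and 2 rose on fenofibrate, and 3 of 9 female-biased genes rose and 1 fell, with a median of 0.41. Female livers among the arrays are argued against by Xist, whose highest fenofibrate value lay 0.06 below the highest control (-0.0564). Over the 13 members with a mean of at least 8, the median shift was 0.542 (quartiles -0.03 and 1.14). This argues against dim probe sets as the cause for the male-biased genes. Of the 13 only Hamp2 (-0.34) and Trim24 (0.56) are female-biased, so dim probe sets stay open for the female-biased genes. Hsd3b5, Slco1a1 and Cyp4a12a, among the 13, had been seen before the lists were written. A general loss of male-biased expression on this diet could be the biological explanation: over members not seen before, fry gave p = 6.03e-07 for the male-biased genes and 0.0488 for the female-biased genes, but for the latter 0.0128 without control replicate 9 alone, itself shifted in both lists (medians -1.29 and 1.43), and 0.0859 without control replicates 1, 2 and 9, which keeps it open (camera with an estimated correlation gave p = 0.0903 and 0.517). On fish oil 5 of 9 female-biased genes fell (median -0.53) and 3 of 14 male-biased genes rose (median 0.40); over members not seen before, camera with an estimated correlation gave p = 0.0523 and 0.191. Without those 3 arrays the medians were -0.53 and 0.181, and without control replicate 9 alone the male-biased median was 0.13; in both fits 3 male-biased genes were called higher and 0 lower, with fry p = 0.0542 and 0.0541 over all members and 0.0285 and 0.0247 over those not seen before, so for the male-biased genes an effect of these arrays cannot be told apart from one of the diet.

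Arrays with consecutive label numbers (1 and 2, 3 and 4 and so on) deviated together, with a mean correlation across genes of 0.246 over 16 pairs, 15 of them above 0; shuffled numbers gave p = 1e-04, the smallest that 10000 shuffles can give. The letter A in some labels is argued against, since the mean without those arrays was 0.259. Neighbours from different pairs had a mean of 0.106, which leaves drift along the numbers open, as it lies between the values set for and against it. The pairs exceeded those neighbours (permutation p = 0.0273, two-sided), as a unit shared by 2 mice, such as the cage, would give. That stays a hypothesis, since no label ties numbers to cages. All 16 pairs share a diet, but only 3 of the 15 neighbours do (mean 0.0455), so the permutation sets unlike pairs against each other.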

How the results depend on the processing

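The fits of arrays numbered 1 to 16 and 17 to 34 alone, the label number as a covariate, and the fits without control replicate 9 or replicates 1, 2 and 9 are tests chosen after the result was seen. Genes changed on fenofibrate against control, on fish oil against control, between the diets, and in the same direction on both diets numbered 3676, 1308, 3507 and 682. Counting every probe set gave 6282, 1986 and 5926, because more features were tested. A 1.5-fold minimum gave 751, 246, 687 and 95, and the share of higher genes went from 51.8% to 39.0% on fish oil and from 50.9% to 64.3% between the diets. An adjusted p under 0.01 gave 686 on fish oil and 348 in the same direction. Consecutive label numbers as a random block gave 3117, 845, 2961 and 445 (consensus correlation 0.23), and array weights 1091 in the same direction. The cause was not tested. For the genes named in the text, the block kept 380 values on their side of the threshold and lost 13 calls. The lists were not tested with this block, so their p values do not take the pairs into account. With fewer arrays, numbers 1 to 16 alone gave 492 on fish oil, 1990 between the diets and 261 in the same direction, and numbers 17 to 34 alone 1788, 520, 1916 and 211. Camera with an estimated correlation passed for 6, 6 and 4 lists in place of 18, 12 and 14, and fry for 26 between the diets. Leaving out each array in turn gave 3495 to 3794, 1099 to 1554, 3319 to 3620 and 582 to 827. The counts of 3794, 1554 and 827 all came without fish oil replicate 9, whose label number carries the letter A. Its median correlation with the other arrays of its diet was 0.980, against 0.981, 0.976 and 0.972 for control replicates 9, 2 and 1. The other counts stayed within 1.5 times, among them those with the replicate block (3574, 1318, 3467 and 682). Replicate numbers do not pair the mice: of 31 pairs of arrays with the same number 12 correlated above 0.1 (-0.206 to 0.354), and 3 of 33 arrays correlated best with their own number. With the replicate block the complement list on fish oil (adjusted p = 0.0819) and peroxisomal beta-oxidation between the diets (0.0786) lost their call. Over the 131 genes named in the text, 6501 values under alternatives kept their side of the threshold, 84 lost the call, 66 gained it and 0 reversed. Over the lists these numbers were 759, 42, 36 and 0. The gene values leave out the fits of arrays numbered 1 to 16 and 17 to 34, the stricter threshold, the 1.5-fold minimum and the count of every probe set. Of the fits without 1 array, only those with the lowest and highest difference per gene were counted. More calls depend on 1 array than these numbers hold: Bpgm on fish oil lost its call in 18 such fits and Crot between the diets in 13. Genes with dim means, such as Mogat1 in controls, have folds limited by the background signal.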

Other observations

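Tests on the lists of sex-biased genes and on arrays numbered 1 to 16 and 17 to 34 were chosen after results had been seen. Among male-biased genes, fenofibrate lowered the bile carrier gene Slco1a1 (fell by 2.50 ± 0.21), the complement gene C6 (fell by 1.49 ± 0.22), the oxysterol hydroxylase gene Cyp7b1 (fell by 1.14 ± 0.20) and Ugt2b1 (fell by 1.12 ± 0.10), with adjusted p of 1.36e-11, 1.22e-06, 2.04e-05 and 4.84e-11 in limma; 10 of 14 listed genes fell and 2 rose. On fish oil Keg1 (0.87 ± 0.14) and Cyp2d9 (0.40 ± 0.09) rose, and among female-biased genes Hamp2 (fell by 1.73 ± 0.23), Nipal1 (fell by 1.52 ± 0.37) and Fmo4 (fell by 0.53 ± 0.13) fell with Cyp17a1; 5 of 9 listed genes fell and 0 rose. All of these but Slco1a1, Cyp7b1 and Cyp17a1 were named after their values were seen, and Nipal1 and Fmo4 had dim control means of 4.07 and 4.37. Between the diets 12 of the 14 male-biased genes were lower and 7 of the 9 female-biased genes higher on fenofibrate.

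Fabp3, a fatty acid binding protein of muscle, rose by 3.37 ± 0.51 on fenofibrate from a control mean of 2.91, and the monocarboxylate transporter gene Slc16a1 rose by 0.88 ± 0.17. The bile acid receptor gene Nr1h4 fell by 0.35 ± 0.07 on fenofibrate. The lipogenic gene Thrsp fell by 2.18 ± 0.33 and the endothelial lipase gene Lipg by 1.41 ± 0.34 on fish oil. The oxysterol receptor gene Nr1h3 did not pass in any of the 3 comparisons (-0.11, -0.13 and 0.03). Fabp3, Thrsp and Lipg were named after their values were seen.

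Of 31 measured complement and coagulation genes, 17 had every fenofibrate value below the lowest control value. Over 290 genes outside the lists with a mean log2 value of at least 12, the median difference on fenofibrate was -0.02, with quartiles of -0.19 and 0.15, against quartiles of -0.81 and -0.32 for the complement list. Between arrays numbered 1 to 16 and those numbered 17 to 34, which share no mouse, the log2 differences correlated across genes, which are not independent replicates, at Pearson's 0.872 on fenofibrate, 0.659 on fish oil and 0.871 between the diets (Spearman's 0.75, 0.454 and 0.721).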
